A study of Homo sapiens with 4 samples.

How the data were processed

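Single-cell RNA sequencing (10x Genomics 3' chemistry, version 3.1 per the labels' protocols) was done on human trophoblast organoids at day 10. The organoids were grown from trophoblast stem cells of the H9 line, an established human embryonic stem cell line. Organoids labelled WT were compared with organoids of cells in which the chemokine receptor gene CCR7 had been knocked out, with 2 libraries per genotype. The labels do not say whether the WT cells are a clone that went through editing. The labels' protocols speak of 2 independent experiments and do not say which library came from which, so p-values measure the spread between these libraries. Per the labels' protocols, organoids were freed from Matrigel, dissociated with papain and passed through a 40 µm strainer, which holds back large multinucleate pieces of syncytium.

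The deposited values were raw UMI counts per gene and barcode. Per the file headers they were made with Cell Ranger 6.1.1, except those of WT replicate 2, whose header names Cell Ranger 4. The genome was GRCh38 (also written hg38), per the submitters' processing notes. The files of 3 libraries held only barcodes with at least 500 UMIs. The deposited matrix of WT replicate 2 held 2712715 columns, of which 990005 had no UMI, and its separate barcode list could not be matched to those columns. Cells of that library were therefore chosen from the matrix itself with the same filter as in the others, which is a difference between libraries before any biology. No step that the labels and headers do not record is assumed here.

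Cells with at least 1000 detected genes and under 20% of UMIs from mitochondrially encoded genes were kept. Scrublet (scanpy 1.11.5) was run per library with an expected doublet rate of 0.8% per 1000 cells. Its automatic threshold called 0.503% of cells in WT replicate 1 and none in the other libraries, so there the cells with the highest scores were removed up to the expected rate, as fixed beforehand for that case. This removed 6, 49, 523 and 188 cells from WT replicates 1 and 2 and knockout replicates 1 and 2. The kept cells numbered 1186, 2424, 7563 and 4665 in the same order, with 32922584, 62364085, 84492472 and 129669627 UMIs.

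The kept cells were clustered in Seurat 5.3.0 (R 4.3.3) on log-normalised values of 2000 variable genes, with 30 principal components, RPCA integration of the 4 libraries and a resolution of 0.5. Clusters were named from marker genes fixed before the data were examined. The scoring of those markers was set after the data were seen. A differentiated class needed 5 raised markers, raised meaning at least 1.5-fold over the mean of the other clusters and more than 5 CPM, a median log2 fold of at least 0.5, and no other class with more raised markers. A cytotrophoblast-like cluster was one left without a differentiated or mitotic name, with 3 markers raised over the differentiated clusters and a median above 0, and no other class leading its top genes. Of the 5 cytotrophoblast-like clusters 4 had at most 1 cytotrophoblast marker raised over the other clusters, so the name rests on the contrast with differentiated cells. That last condition was added after a cluster of low-quality cells had received a name under a stricter cell filter, and it changed no name in the clustering reported here. A cluster led by mitotic genes was set apart, and 2 clusters stayed unnamed. The class counted under the extravillous lineage rests on 5 raised markers of the trophoblast cell column and is called column-like in the text.

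UMI counts were summed per library over all kept cells and over the cells of each class, with at least 30 cells required. The sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test) with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. CPM values in the text are TMM-scaled unless called pooled. Gene lists, 36 of them, were fixed before the data were examined. They were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, wherever at least 3 members were measured, and camera with an estimated correlation and fry were run beside it. Lists overlap, and medians of log2 fold change are those of the camera fit. The difference in knockout effect between classes was tested as an interaction in one edgeR fit of the 3 classes, with library as a block. That fit scales all its sums together, so its CPM values differ somewhat from those of the fits of single classes. Shares of cells were compared by a two-sided exact permutation test over libraries, whose smallest p with 2 against 2 is 0.333, and each share has an exact 95% binomial interval that covers counting error only. For the share of cycling cells each cell was thinned to 3000 UMIs. A fold against a group with no UMI is a lower bound set at 3 counts over the group. A fold against 1 to 3 counts has an exact 95% counting interval.

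Named genes follow a rule fixed beforehand. It takes CCR7 and its ligands CCL19 and CCL21, then the genes past the threshold with at least 10 CPM in one group and both knockout libraries on the same side of both WT libraries. Of these, the 10 largest changes each way are named over all cells and 5 each way per class. Up to 4 members of each list described are named too. The comparison between classes used a looser form, at least 10 CPM in 1 library of either class, with 5 genes named each way. Gene positions are from GENCODE on GRCh38, counted from 1. Medians along chromosomes used windows of 10 Mb with at least 10 tested genes and 2000 bootstrap draws. Genes on in one genotype and off in the other were defined after the data were seen. They were genes past the threshold with both knockout libraries on the same side of both WT libraries. They also had at least 5 CPM in one group and at least 50 times less in the other. XIST and Y-linked genes were left out of every test and table.

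The tests were checked on simulated counts drawn from the real means and library sizes, here without an effect shared by replicates of one number. Over all cells, with 15538 genes, the edgeR fit recovered 82% of 94 genes changed 8-fold and 4.17% of 96 genes changed 2-fold, with 2 false calls among 83. In cytotrophoblast-like cells it recovered 85% of 97 genes changed 8-fold and 3.16% of 95 changed 2-fold. In syncytiotrophoblast-like cells the shares were 86% of 96 and 7.29% of 96, and in column-like cells 93% of 98 and 7.37% of 95, there with 8 false calls among 106. The alternatives tried were DESeq2 1.42.0, size factors in place of TMM, no filter on low counts, the replicate number as a block, each library left out in turn, other cell filters, no doublet removal, thinned cells, another resolution, no integration and another prior count.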

Results

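Trophoblast organoids model the early placenta, in which cytotrophoblast, the proliferating progenitor, gives rise to hormone-producing syncytiotrophoblast by cell fusion and to invasive extravillous trophoblast by way of cell columns. Single cells of organoids at day 10 were sequenced from H9-derived trophoblast stem cells labelled WT (2 libraries) and from cells with the chemokine receptor gene CCR7 knocked out (2 libraries). The design asks what the loss of CCR7 does to the cell types of the organoid and to the genes each type expresses. With 1 line named per genotype, a difference between the lines goes with the knockout in every comparison below. After filtering, WT replicates 1 and 2 held 1186 and 2424 cells, and knockout replicates 1 and 2 held 7563 and 4665. Median depth per cell was 21958.5 and 19162 UMIs in WT and 9381 and 24506 UMIs in the knockout, so knockout replicate 1 was the shallowest per cell. Among barcodes with at least 500 UMIs the median mitochondrial share was 37.5% in WT replicate 1, 17.7% in WT replicate 2 and 17.9% and 13% in the knockout. Those barcodes had a median of 745 UMIs in WT replicate 2, against 6961.5 in WT replicate 1 and 7066 and 17081 in the knockout. The 17.7% is therefore not comparable with the other shares. With a limit of 50% mitochondrial UMIs the medians were 21.7% and 20.8% in WT and 16.1% and 11.7% in the knockout. In the kept cells they were 12.6% and 10.9% in WT and 13.4% and 10.3% in the knockout.

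CCR7 (ENSG00000126353, chromosome 17, 40553769 to 40565472 on GRCh38), the receptor that guides immune cells toward its ligands CCL19 and CCL21, fell in the knockout by 3.05 on the log2 scale (SE 0.28, n = 2 per genotype, edgeR quasi-likelihood adjusted p = 0.0124). Its level was 27.9 and 28.7 CPM in WT and 3.74 and 3.11 CPM in the knockout libraries. WT replicates 1 and 2 had 946 and 1766 CCR7 UMIs, and knockout replicates 1 and 2 had 306 and 409. At least 1 CCR7 UMI was seen in 41.2% of cells in WT replicate 1 (exact 95% interval 38.4% to 44.1%) and 36.8% in WT replicate 2 (34.9% to 38.8%). The same share was 3.73% (3.31% to 4.18%) in knockout replicate 1 and 7.22% (6.50% to 8.0%) in knockout replicate 2. No cell class was fixed as lacking CCR7, so the part of these shares owed to free RNA is unknown. In WT the receptor was higher in syncytiotrophoblast-like cells, at 58.5 and 77.9 CPM, than in cytotrophoblast-like cells, at 27.3 and 22.4 CPM. It fell within each class, by 3.25 in cytotrophoblast-like, 3.33 in syncytiotrophoblast-like and 3.14 in column-like cells on the log2 scale (edgeR adjusted p = 0.0137, 0.00833 and 0.0467). The labels do not give the deleted part of the gene, and a 3' tag outside it can persist, so the remaining UMIs do not measure leftover protein. The ligands were all but absent, with 1 UMI of CCL19 in knockout replicate 1 and none elsewhere, and no UMI of CCL21, where 3 counts would equal 0.0911 CPM in the library with the fewest UMIs.

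Clustering separated cytotrophoblast-like cells, syncytiotrophoblast-like cells, a column-like class and mitotic cells. Syncytiotrophoblast-like clusters were led by HOPX, TPPP3, INSL4 and TBX3 in one and by LEP, CGB3, PSG3 and CGA in the other, genes of placental hormones and syncytial differentiation. The column-like cluster was led by TUBB2A, KRT14, NPPB and KRT17. It had 5 column and 2 extravillous markers raised, with HLA-G at 49.3 CPM, a level not above the 60.7 CPM of a cytotrophoblast-like cluster, so mature extravillous trophoblast was not resolved. Cytotrophoblast-like clusters included one led by DDIT4, STC2 and P4HA1, genes known to respond to low oxygen and stress. Of the 2 unnamed clusters, the one led by CCKBR, MT2A and CRIP1 held 1.94% and 1.82% of WT cells and 7.77% and 4.07% of knockout cells. The other, led by LRRC75A and PRR9, went the opposite way, with 11.6% and 4.08% of WT cells and 3.29% and 2.77% of knockout cells.

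Syncytiotrophoblast-like cells made up a larger share of the knockout libraries and column-like cells a smaller one. Syncytiotrophoblast-like cells were 2.78% and 7.43% of WT cells and 11% and 17.9% of knockout cells, a mean of 5.10% ± 3.28 against 14.4% ± 4.86 (SD, n = 2 each). Column-like cells were 4.89% and 4.21% in WT and 1.41% and 1.26% in the knockout, a mean of 4.55% ± 0.483 against 1.34% ± 0.106 (SD, n = 2 each). Cytotrophoblast-like cells were 70.0% and 72.8% in WT and 66.2% and 63.3% in the knockout, and mitotic cells 8.77% and 9.69% against 10.4% and 10.7%. For these 4 classes both knockout libraries lay outside both WT libraries, and the two-sided exact permutation p was 0.33, the smallest that 2 against 2 can give. CGB3, which leads one syncytiotrophoblast-like cluster, itself differed between genotypes, and the cluster led by HOPX and TPPP3 held 2.28%, 5.28%, 8.26% and 12.2% of cells in WT replicates 1 and 2 and knockout replicates 1 and 2. Large syncytium does not pass a 40 µm strainer, and depth and mitochondrial loss differed between the libraries, so the shares are of the cells that were recovered. The share of cycling cells, each thinned to 3000 UMIs, was 38.2% and 45.2% in WT and 40.0% and 48.8% in the knockout (two-sided exact permutation p = 0.667). Without thinning it was 72.8% and 78.3% against 66.5% and 85.5%, and thinning left out 10, 167, 241 and 64 cells. Free RNA enters such calls, and its share per cell was not measured.

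**Figure D1:**
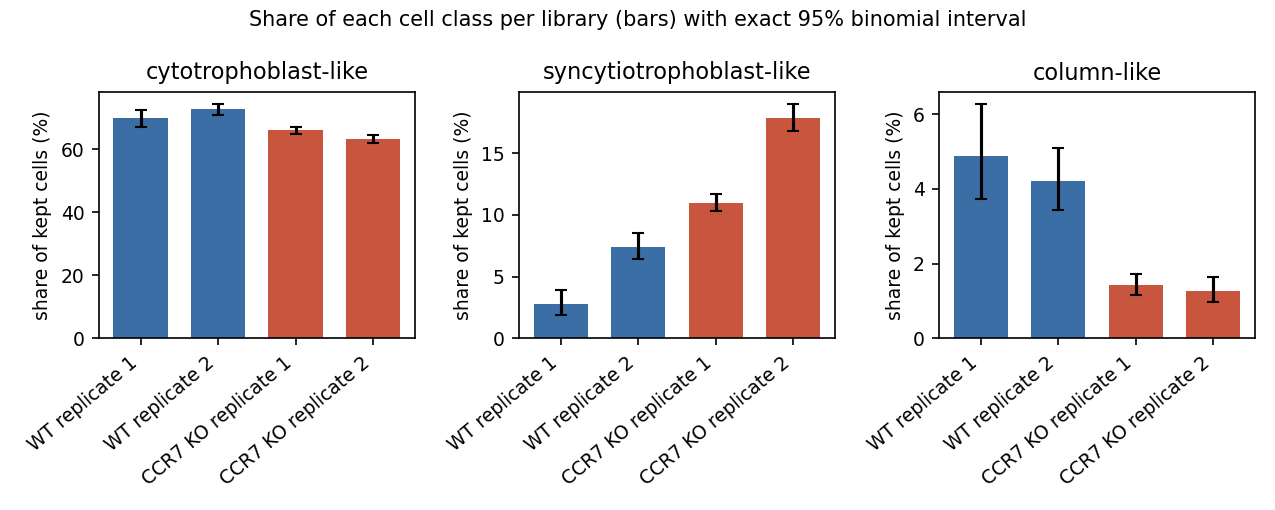
Share of kept cells (y axis, percent) in 3 cell classes for each of the 4 libraries (x axis, WT in blue and CCR7 knockout in red), where bars are shares and error bars exact 95% binomial intervals. Knockout bars for syncytiotrophoblast-like cells stand at 11% and 17.9%, above 2.78% and 7.43% in WT, and those for column-like cells at 1.41% and 1.26%, below 4.89% and 4.21%.

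Over all cells, the genes that changed most were on in one genotype and near 0 in the other. SOHLH2, a transcription factor of germ cells, rose from 0.325 and 0.114 CPM in WT to 62.1 and 54.4 CPM in the knockout (log2 fold change 8.17, SE 0.52, edgeR adjusted p = 0.00616). MAGEA4, a cancer-testis antigen, fell from 23.6 and 62.4 CPM to 0.0122 and 0.076 CPM (log2 fold change −9.72, SE 0.85, edgeR adjusted p = 0.012). MGMT, which repairs alkylated guanine in DNA, and the zinc finger gene ZNF22 fell by 8.85 and 9.11 on the log2 scale (edgeR adjusted p = 0.00291 for each). HSPB1, a small heat shock protein, fell from 193 and 256 CPM to 1.47 and 2.23 CPM (log2 fold change −6.92, SE 0.40, edgeR adjusted p = 0.00498). CGB3, a beta subunit gene of chorionic gonadotropin, was 0.472 and 3.61 CPM in WT and 206 and 751 CPM in the knockout (log2 fold change 7.83, SE 1.18, edgeR adjusted p = 0.0434). Its near-identical paralogs share reads with it, so the split between copies is uncertain.

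In all, 206 of 16060 genes changed over all cells, 97 higher and 109 lower in the knockout (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05, n = 2 per genotype). THUMPD2, an RNA methyltransferase gene, had no UMI in WT and was at least 649-fold higher in the knockout, at 8.56 and 27.9 CPM. The serine protease gene PRSS21 had 2 UMIs in WT, and its pooled level was 553-fold higher in the knockout (95% counting interval 153 to 4566). Other increases were AC004556.3 on an unplaced sequence, the lincRNA AC022784.1, the testis-type oxidase subunit COX7B2, the GTPase gene RAB38, PRR9 and the peptidase gene TRHDE, with log2 fold changes from 4.96 to 9.29. Other decreases were the matrix protein gene SMOC2 (log2 fold change −8.80), the autophagy gene MAP1LC3A on chromosome 20 (−7.23), C19orf81 (−4.94), the cytokine signalling inhibitor SOCS2 (−4.74) and the let-7 regulator LIN28A (−4.69). HLA-B, which presents peptides to T cells, fell by 5.52 while HLA-A was listed at 0 in both WT libraries and at 2.74 and 2.73 CPM in the knockout (edgeR adjusted p = 0.0458 and 0.0178). These class I genes share reads, and counts against one reference allele can miss another, so their levels are uncertain.

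**Figure D2:**
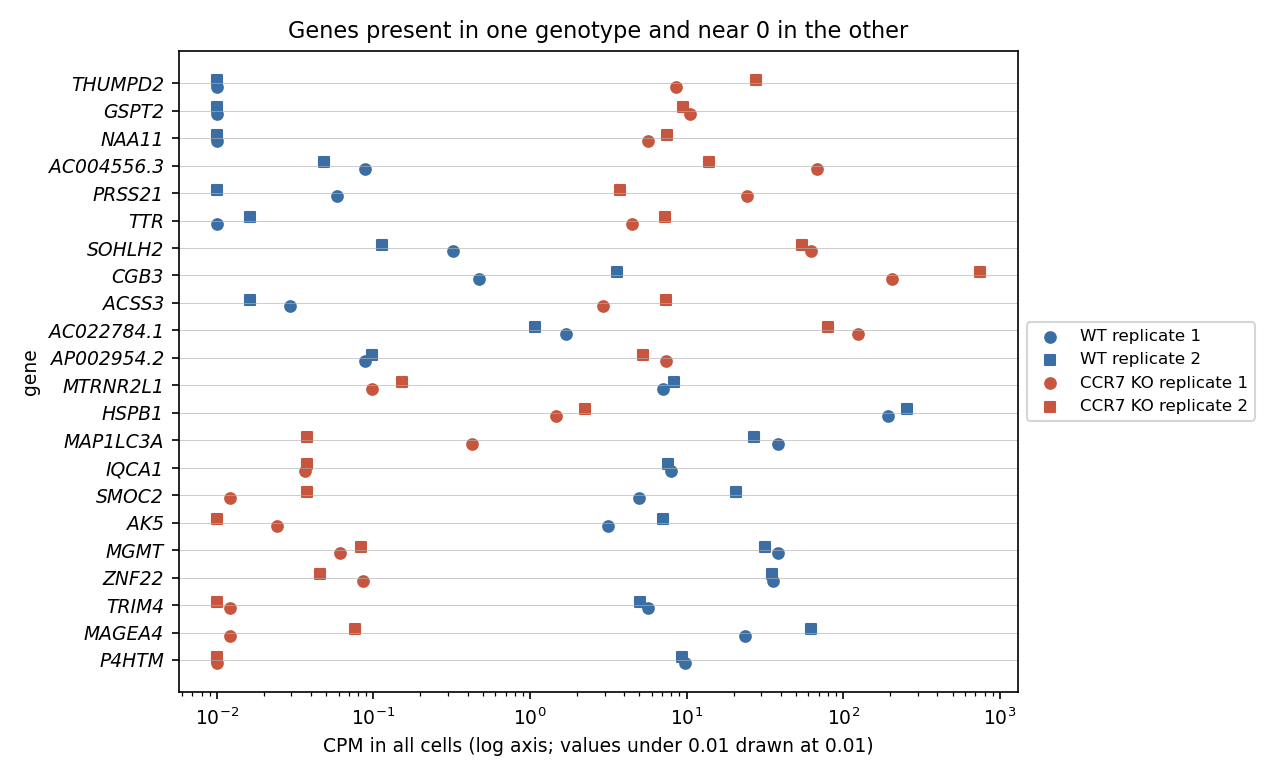
Level over all cells (x axis, CPM on a log axis, values under 0.01 drawn at 0.01) of 22 genes present in one genotype and near 0 in the other (y axis), with WT libraries in blue and CCR7 knockout libraries in red, circles for replicate 1 and squares for replicate 2. Of these genes 11 were off in the knockout and 11 off in WT. For every gene both points of one genotype lie to the right of both points of the other, which was a condition for choosing the genes.

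Among the fixed lists, markers of syncytiotrophoblast were higher over all cells in the knockout, while hypoxia and extracellular matrix genes were lower. The syncytiotrophoblast list rose with a median log2 fold change of 1.67 over 20 measured genes (camera adjusted p = 0.00165), and 1 of them, CGB3, passed over all genes, against 3 adjusted over the list alone. CGA, the alpha subunit of the hormone, stood at 403 and 3192 CPM in WT and 6037 and 11413 CPM in the knockout without passing (edgeR adjusted p = 0.214). The cell fusion list rose by a median of 0.74 over 12 genes (camera adjusted p = 0.0295), with none past over all genes and 1 adjusted over the list alone. Both lists move with the larger syncytiotrophoblast-like share. S phase genes rose by a median of 0.46 over 42 genes (camera adjusted p = 0.000931), 0 past over all genes and 7 higher adjusted over the list alone. NASP, HELLS and GMNN of this list rose by 0.67, 0.87 and 0.84 without passing (edgeR adjusted p = 0.199, 0.179 and 0.155). Nuclear-encoded oxidative phosphorylation genes rose by a median of 0.34 over 38 and cholesterol synthesis genes by 0.65 over 21 (camera adjusted p = 0.0185 and 0.0311), with none past in either way of adjusting. Hypoxia genes fell by a median of 0.59 over 20 (camera adjusted p = 0.00365), 1 past over all genes and 5 lower adjusted over the list alone. The one was CA9, a carbonic anhydrase induced by low oxygen (log2 fold change −5.20). Extracellular matrix and invasion genes fell by a median of 0.68 over 24 (camera adjusted p = 0.000931), with the collagen gene COL1A2 past over all genes and 8 lower adjusted over the list alone. Each of these 7 lists had adjusted p = 0.829 with an estimated correlation, so none of the calls holds under that form of the test. Without WT replicate 1 only the matrix list passed, and without knockout replicate 2 only the matrix and hypoxia lists.

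Single members of other lists also passed over all cells. BST2, an interferon-induced restriction factor, fell by 3.96 while MX1, another interferon target, rose by 5.34 (edgeR adjusted p = 0.0206 and 0.0451), and the interferon list as a whole had a median of 0.02 (camera adjusted p = 0.855). PSMB8, a subunit of the immunoproteasome, rose by 3.66, and PLAC8 of the extravillous list fell by 2.83 (edgeR adjusted p = 0.0304 for both). The imprinted gene ZFAT rose from 5.67 and 4.03 to 85.6 and 56.4 CPM (log2 fold change 3.88, edgeR adjusted p = 0.0124). The Wnt antagonist SFRP1 fell by 4.26 and the growth factor binding protein IGFBP3 by 4.54 (edgeR adjusted p = 0.0313 and 0.049). Of the chemokine list, which sits closest to the receptor, 11 genes were measured with a median of −0.78 (camera adjusted p = 0.101), and CCR7 was its one gene past over all genes. ERK feedback genes had a median of 0.29 and NF-kappa B targets of −0.16 (camera adjusted p = 0.663 and 0.992). DUSP5 and CCND1 of the first list had log2 fold changes of 2.32 and 2.58 without passing (edgeR adjusted p = 0.0819 and 0.117). The heat shock and dissociation list had a median of 0.85 but a mean of 0.11, pulled by HSPB1 (camera adjusted p = 0.135). Lists of amnion, pluripotency, fibroblast and endoderm markers, for cells the organoids could hold besides trophoblast, did not pass (camera adjusted p from 0.189 to 0.724). Single members did, with IGFBP3 of the amnion, LIN28A of the pluripotency, COL1A2 of the fibroblast and GATA4 of the endoderm list lower and TTR of the endoderm list higher over all genes.

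**Figure D3:**
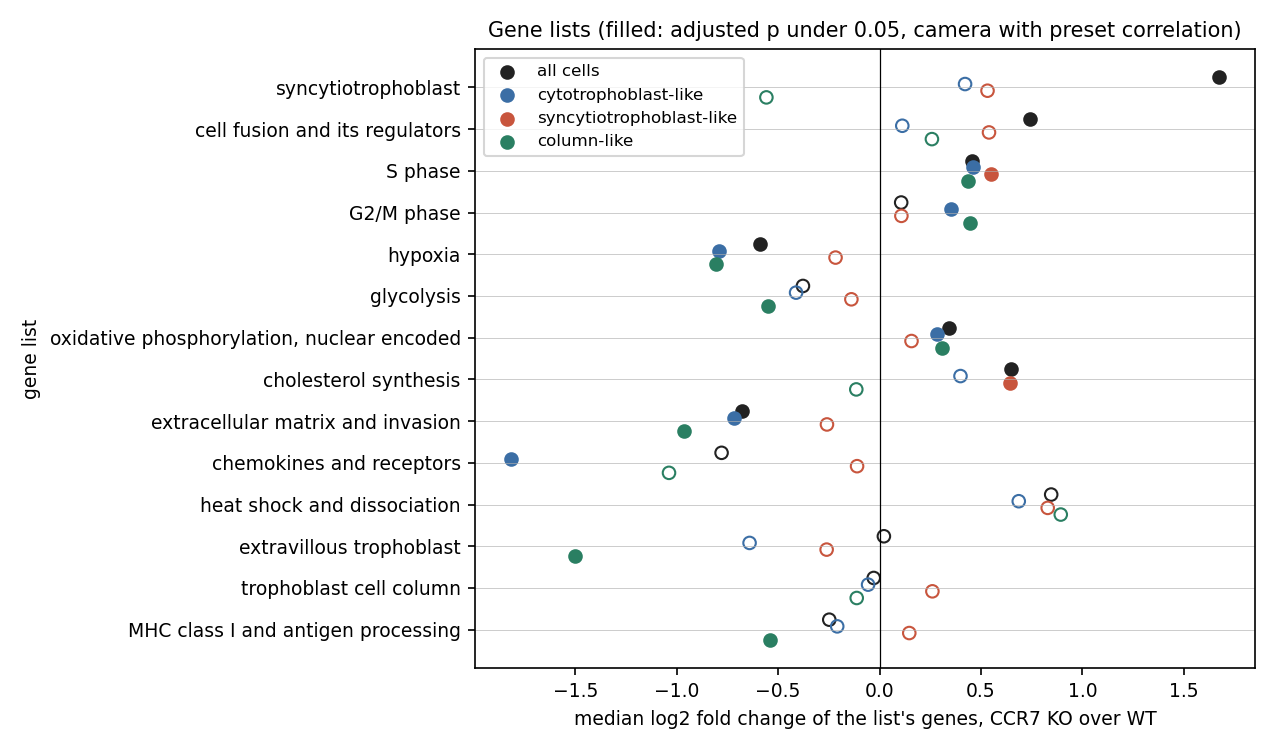
Median log2 fold change, CCR7 knockout over WT (x axis), of 14 gene lists (y axis) over all cells (black) and within cytotrophoblast-like (blue), syncytiotrophoblast-like (red) and column-like cells (green), where filled points passed adjusted p under 0.05 by camera with a preset correlation and open points did not. S phase lies right of 0 in all 4 populations, from 0.44 to 0.55, and hypoxia lies left of 0, from −0.81 to −0.22.

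Within cytotrophoblast-like cells, the progenitors, the strongest changes were again genes switched between genotypes. HSPB1 fell from 167 and 189 CPM in WT to 0.171 and 0.19 CPM in the knockout (log2 fold change −9.91, SE 0.38, edgeR adjusted p = 0.000484), and MGMT fell by 8.89 (SE 0.41, edgeR adjusted p = 0.00062). ZNF22 had 2 UMIs in the knockout and was 2116-fold lower there (95% counting interval 585 to 17480). GSPT2, a translation termination factor gene, had no UMI in WT and was at least 225-fold higher in the knockout, and THUMPD2 at least 460-fold. SOHLH2 rose by 8.21 (SE 0.49, edgeR adjusted p = 0.00273). In this class 250 of 14724 genes changed, 108 higher and 142 lower (edgeR quasi-likelihood, Benjamini-Hochberg, n = 2 per genotype).

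The cytotrophoblast-like cells of the knockout had higher cell cycle lists and lower hypoxia, matrix and chemokine lists. S phase genes rose by a median of 0.46 over 42 genes and G2/M genes by 0.35 over 52 (camera adjusted p = 7.13e-05 and 0.00714). FEN1, the flap endonuclease of lagging-strand synthesis, passed over all genes (log2 fold change 1.68, edgeR adjusted p = 0.0464, on chromosome 11), and 8 S phase genes and no G2/M gene were higher adjusted over the list alone. Hypoxia genes fell by a median of 0.79 over 19 (camera adjusted p = 7.13e-05), with NDRG1 (log2 fold change −4.40) and CA9 (−4.70) past over all genes and 10 lower adjusted over the list alone. HK2, which starts glycolysis, fell from 30.2 and 26.5 to 9.88 and 8.82 CPM (log2 fold change −1.60, edgeR adjusted p = 0.0421), while the glycolysis list had a median of −0.41 (camera adjusted p = 0.119). Matrix genes fell by a median of 0.72 over 21 (camera adjusted p = 0.000192), none past over all genes and 5 lower adjusted over the list alone. The chemokine list, which holds CCR7, fell by a median of 1.82 over 8 genes (camera adjusted p = 0.00297), with CCR7 past over all genes and 3 lower adjusted over the list alone. Oxidative phosphorylation genes rose by a median of 0.28 over 38 (camera adjusted p = 0.0153), with none past in either way of adjusting. All 6 lists had adjusted p = 0.88 with an estimated correlation. The class also held its clusters in other shares, so its sums mix a shift between clusters with changes inside them. The cluster led by the histone genes HIST1H1D and HIST1H1B was a mean of 11.8% of WT and 18.8% of knockout cells, and that led by NTHL1, FABP5 and PAGE4 9.77% and 18.1%. The cluster led by IGKC, MYLPF and CAV1 was 17.4% and 11.2%, and that led by DDIT4 19.3% and 6.21%. The syncytiotrophoblast list had a median of 0.42 in this class (camera adjusted p = 0.62), with CGB3 higher and the BMP antagonist GREM2 lower. CDKN1A, an inhibitor of cell cycle kinases, fell by 2.97, and TWIST1, a transcription factor of mesenchymal transition, rose by 2.74 (edgeR adjusted p = 0.0357 and 0.0377).

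Syncytiotrophoblast-like cells of the knockout carried more CGB3 and KISS1 transcript per cell sum than those of WT. CGB3 rose from 14.4 and 35.6 to 1167 and 3294 CPM (log2 fold change 6.37, SE 0.66, edgeR adjusted p = 0.0086), and KISS1, which encodes a placental peptide hormone, from 11 and 10.1 to 137 and 81.5 CPM (3.39, SE 0.39, edgeR adjusted p = 0.0135). TTR, the thyroid hormone carrier transthyretin, had no UMI in WT and was at least 70.2-fold higher in the knockout, and SOHLH2 at least 34.4-fold. HSPB1 fell from 745 and 725 to 7.55 and 8.87 CPM (log2 fold change −6.48, SE 0.35, edgeR adjusted p = 0.000401). AC022784.1 and AP002954.2 rose by 6.16 and 5.46, and the changes of ZNF22 and MAP1LC3A were −7.33 and −6.24. MAGEA4 had 1 UMI and MGMT 2 UMIs in the knockout, 1091-fold lower (95% counting interval 193 to 43346) and 271-fold lower (73.0 to 2275), respectively. FOSL1, a transcription factor of trophoblast invasion on chromosome 11, rose by 2.51 and BST2 fell by 5.17 (edgeR adjusted p = 0.0498 and 0.0373). In this class 62 of 11591 genes changed, 24 higher and 38 lower (edgeR quasi-likelihood, Benjamini-Hochberg, n = 2 per genotype), and the class held 33 cells in WT replicate 1.

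Of the lists in syncytiotrophoblast-like cells, S phase genes rose by a median of 0.55 over 42 genes (camera adjusted p = 0.000108), none past over all genes and 1 higher adjusted over the list alone. Cholesterol synthesis genes rose by a median of 0.64 over 21 (camera adjusted p = 0.00815), none past over all genes and 1 higher adjusted over the list alone, while FDPS and IDI1 rose by 0.71 and 0.96 without passing (edgeR adjusted p = 0.36 and 0.17). The endoderm list rose over its 3 measured genes, by a median of 0.94 (camera adjusted p = 0.0322), with TTR the one past either way and GATA6 at 0.97 with no more than 2.62 CPM in any library. These lists had adjusted p = 0.771 with an estimated correlation, and without WT replicate 2 or without knockout replicate 2 the number past fell to 1. The syncytiotrophoblast list itself had a median of 0.53 within the class (camera adjusted p = 0.252), and CGA a log2 fold change of 1.14 (edgeR adjusted p = 0.277).

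Column-like cells of the knockout had lower SFRP1, LAMB3 and TGFB1 and higher MEST, PHLDA2, CDKN1C and ZFAT. SFRP1 stood at 31.3 and 33.8 CPM in WT and had no UMI in the knockout, at least 34.4-fold lower. LAMB3, a laminin chain of cell adhesion, fell (log2 fold change −2.77), as did the growth factor gene TGFB1 (−3.77) and COL1A2 (−7.36) (edgeR adjusted p = 0.0467, 0.0484 and 0.0484). The imprinted gene MEST rose, at 4.04 and 19.1 CPM in WT and 139 and 375 CPM in the knockout (log2 fold change 4.43, SE 0.69, edgeR adjusted p = 0.0192). PHLDA2 and CDKN1C, which restrain placental growth and cell division, rose by 2.34 and 3.09 (edgeR adjusted p = 0.0192 and 0.0231), and ZFAT by 3.62 (edgeR adjusted p = 0.016). Genes switched between genotypes were the largest changes here too. AC004556.3 was at least 51.2-fold, THUMPD2 at least 35.8-fold, SMPDL3B at least 28.4-fold and GSPT2 at least 19.9-fold higher, while MAGEA4 was at least 65.0-fold, MAP1LC3A at least 62.5-fold and MGMT at least 36.4-fold lower. SOHLH2 had 1 UMI in WT and was 185-fold higher in the knockout (95% counting interval 32.6 to 7368), and HSPB1 had 1 UMI in the knockout and was 940-fold lower there (168 to 37155). In this class 68 of 9120 genes changed, 34 higher and 34 lower (edgeR quasi-likelihood, Benjamini-Hochberg, n = 2 per genotype), from 58 and 102 WT cells and 107 and 59 knockout cells.

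In the reported fit more lists passed in column-like cells, 10 of 33, than in the other populations. With thinned cells 3 passed there against 6 over all cells, and no test compared the populations. The extravillous list fell by a median of 1.50 over 9 genes (camera adjusted p = 0.00165), none past over all genes and 6 lower adjusted over the list alone, with HLA-G at −1.62 and FSTL3 at −2.05. Matrix genes fell by a median of 0.96 over 19, hypoxia genes by 0.81 over 17, glycolysis genes by 0.55 over 20, MHC class I genes by 0.54 over 9 and Wnt targets by 0.39 over 12 (camera adjusted p = 1.77e-06, 3.92e-06, 0.000282, 0.0133 and 0.0248). Of these, 2 matrix genes, 1 MHC gene (HLA-B, −6.29) and 1 Wnt gene passed over all genes, with none of hypoxia or glycolysis, and 7, 2, 1, 6 and 4 in the same order were lower adjusted over the list alone. S phase genes rose by a median of 0.44 over 40, G2/M genes by 0.45 over 50, oxidative phosphorylation genes by 0.31 over 38 and imprinted genes by 0.59 over 13 (camera adjusted p = 0.000906, 0.000925, 0.011 and 0.012). Of the imprinted genes 4 were higher over all genes, and 4 higher and 2 lower adjusted over the list alone, while no gene of the other 3 lists passed either way. With an estimated correlation all 10 calls were lost, at adjusted p = 0.574 for G2/M, adjusted p = 0.62 for oxidative phosphorylation and adjusted p = 0.486 for the other 8. Without knockout replicate 2 the number of lists past fell to 5.

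The effect of the knockout was also compared between classes in one fit with library as a block. It differed between syncytiotrophoblast-like and cytotrophoblast-like cells for 413 of 13142 genes, 359 with the more positive change in syncytiotrophoblast-like cells and 54 with the more negative one (edgeR quasi-likelihood interaction, Benjamini-Hochberg). Between column-like and cytotrophoblast-like cells it differed for 14 genes, 9 and 5 in the same order. With 1 library left out the first count was 108 to 488 and the second 27 to 109.

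Changes were also laid out along the chromosomes, since neighbouring genes moved together in places. In cytotrophoblast-like cells the median log2 fold change of the 378 tested genes of chromosome 20 was −0.51 (bootstrap 95% interval −0.57 to −0.43), and all 7 windows of 10 Mb lay between −0.56 and −0.42. Chromosome 11 had a median of 0.33 and chromosome 10 of 0.19, and on chromosome 11 the windows from 50 to 120 Mb were higher while those from 120 Mb were lower. The medians in syncytiotrophoblast-like cells were −0.56, 0.38 and 0.21 for chromosomes 20, 11 and 10, and in column-like cells −0.57, 0.45 and 0.15.

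**Figure D4:**
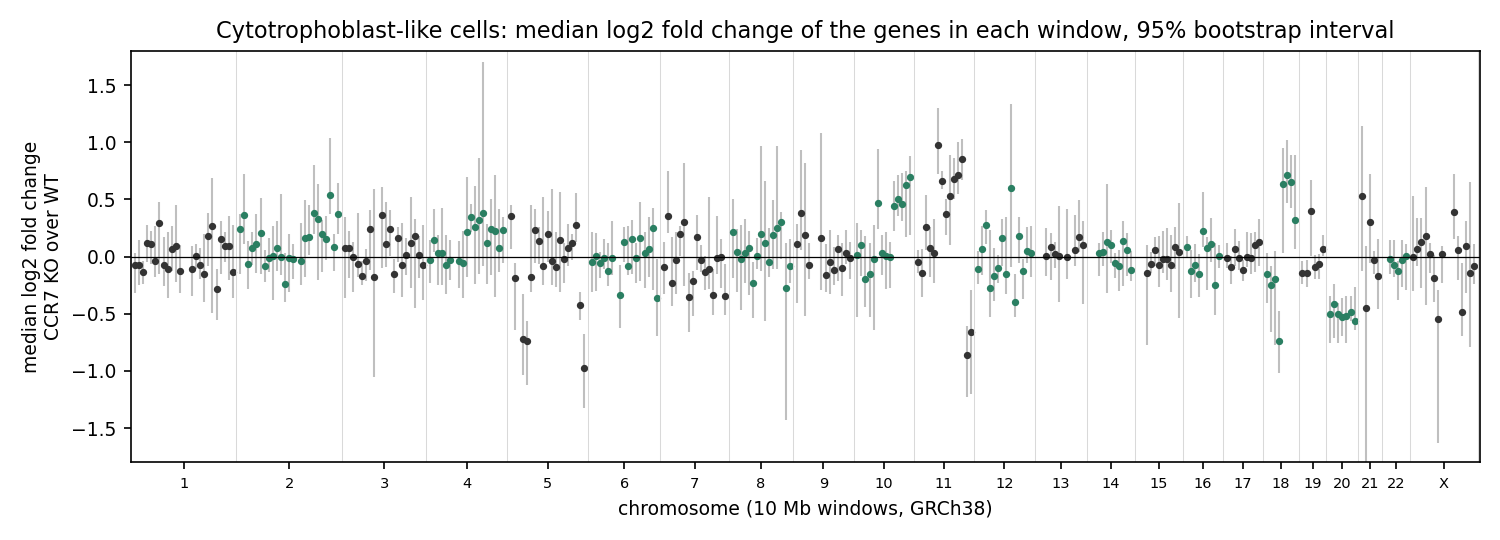
Median log2 fold change, CCR7 knockout over WT, in cytotrophoblast-like cells (y axis) of the genes in each window of 10 Mb along the chromosomes (x axis, GRCh38), where points are medians, colours alternate between chromosomes and lines are 95% bootstrap intervals. The 7 windows of chromosome 20 lie between −0.56 and −0.42, and those of chromosome 11 from 50 to 120 Mb lie between 0.37 and 0.98.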

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

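The tests of the mix of cell classes, of the cell clones, of a looser mitochondrial filter and of heat shock genes were chosen after the results they bear on were seen.

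The knockout effect differed between syncytiotrophoblast-like and cytotrophoblast-like cells for 413 genes and between column-like and cytotrophoblast-like cells for 14 genes, by an interaction term in edgeR (Benjamini-Hochberg adjusted p under 0.05). The 14 became 27 to 109 with 1 library left out. Toward syncytiotrophoblast-like cells, the log2 fold change was higher by 4.25 for ALPL, alkaline phosphatase, by 3.94 for TCL1B, by 3.54 for HSPB1, by 3.49 for CRIP1 and by 3.37 for CDKN1A. ALPL was low, at 0 and 1.42 CPM in WT and 5.38 and 11.2 CPM in knockout syncytiotrophoblast-like cells. It did not exceed 0.358 CPM in cytotrophoblast-like cells. TCL1B moved in opposite directions, with 36.3 and 39.0 CPM in WT and 103 and 70.5 CPM in knockout syncytiotrophoblast-like cells against 3.87 and 5.48 CPM and 1.0 and 0.539 CPM in cytotrophoblast-like cells. CPM values of these comparisons are scaled in the joint fit and differ somewhat from those of single classes. HSPB1 was lower in the knockout in both classes, with 8.47 and 10.3 CPM left in syncytiotrophoblast-like and 0.161 and 0.175 CPM in cytotrophoblast-like cells. The difference had the other sign for LINC01819 (−1.77), TMEM140 (−1.70), HOXB4 (−1.54), AL139260.1 (−1.40) and the kinase gene ICK (−1.34), which was 70.2 and 51.1 CPM in WT and 22.0 and 20.8 CPM in knockout syncytiotrophoblast-like cells.

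In column-like cells the change was more positive than in cytotrophoblast-like cells for the cell cycle inhibitor CDKN1C by 3.6, FYB1 by 2.14, WNT6 by 1.71, BTG3 by 1.34 and the growth factor gene MDK by 1.25. CDKN1C was 10.2 and 5.22 CPM in WT and 44.9 and 85.6 CPM in knockout column-like cells. It was more negative for KISS1 (−3.13), PSG3 (−2.31), CNST (−1.55), RDH13 (−1.46) and S100A4 (−1.42). KISS1 was 45.7 and 136 CPM in WT and 34.8 and 12.5 CPM in knockout column-like cells, against a rise in syncytiotrophoblast-like cells, a contrast between those classes that was not tested.

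Of the 22 genes on in one genotype and off in the other, AP002954.2 had no listed position. The rest lay on 17 sequences, counting the unplaced one that holds AC004556.3, with at most 2 on any. A lost segment would lower their neighbours too. Expressed genes within 1 Mb of the genes off in the knockout had a median log2 fold change of −0.216 (bootstrap 95% interval −0.288 to −0.128, 183 genes). This small pooled fall argues against a loss of such segments around all of these genes, though its interval excludes 0. Many of the 183 lay near P4HTM, from −2.50 to 1.31, or TRIM4, while those of SMOC2 ran from −5.38 to −0.0491. Around MAP1LC3A all but EIF6 and EIF2S2 were below 0, on chromosome 20, where expression was lower along the whole chromosome. Around HSPB1 all but MDH2 were below 0. The bootstrap draws genes singly, though neighbouring genes can move together, so its interval may be too narrow. Loss around single genes, shorter deletions and the genes off in WT were not tested. The median ratio between the log2 fold change in cytotrophoblast-like cells and that over all cells was 0.986, for 20 genes. The genes were chosen on sums in which cytotrophoblast-like cells are the largest class, so a ratio near 1 was likely beforehand. All 20 also passed the threshold within that class, which argues against a different mix of classes as their only source. TTR and AP002954.2 were not tested in that class, and rose by 11.5 and 5.46 on the log2 scale within syncytiotrophoblast-like cells. A difference between cell clones that goes with the genotype stays open, since 14 of the 14 genes tested in the 3 classes moved at least 8-fold the same way in each, and the labels name 1 line per genotype. An effect of CCR7 itself and a lasting difference between clones, such as in DNA methylation, may each give this pattern and cannot be told apart here.

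The larger syncytiotrophoblast-like share in the knockout, 2.83 times that of WT, was weighed against the loss of cells, and the difference was 5.90 to 12.8 percentage points and the ratio 1.94 to 5.19 with 1 library left out. Loss of WT cells with 20% to 50% mitochondrial UMIs is argued against, since with up to 50% the ratio was 2.87 (1.90 to 5.87 with 1 library left out). That filter still passed only 2566 of 4444 barcodes in WT replicate 1, against 12225 of 15119 and 6161 of 7691 in the knockout. Loss of cells beyond that filter or before capture was therefore not tested. In thinned cells, the share with at least 3 syncytiotrophoblast markers was 3.06% and 9.66% in WT and 11.8% and 20.5% in the knockout. The ratio was 2.54 (1.68 to 5.29), so deeper sequencing is argued against as the source of that marker difference. The markers include CGB3 and KISS1, which were higher within the class in the knockout, so the ratio does not measure the share of cells alone. Free RNA of syncytiotrophoblast-like cells could add marker UMIs to other cells, and the rise outside the class was 24.7% of that among all cells, but from −27.0% to 31.1% over the pairs of libraries, which leaves it open. A higher rate of differentiation in the knockout remains a candidate explanation, with 2 libraries per genotype and a strainer that holds back syncytium.

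The lower hypoxia list in knockout cytotrophoblast-like cells was weighed against stress and cell state. Different mitochondrial shares per cell are argued against, since in the 3 bins of that share the median nearest 0 was −0.535 (widest bounds −1.37 to −0.270). Fewer cells of the cluster led by DDIT4 and P4HA1, at 21.7% and 16.8% of WT and 8.58% and 3.84% of knockout cells, may account for part of it, with medians of −0.332 (−0.996 to −0.152) outside that cluster and −0.619 (−1.11 to −0.00840) inside it, where its loss explains no fall. Stress of dissociation stays open, as the heat shock list had a median of 0.686 (−0.593 to 1.14), an interval that includes both signs. Oxygen supply and organoid size were not measured.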

How the results depend on the processing

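Populations are given in the order all, cytotrophoblast-like, syncytiotrophoblast-like and column-like cells unless named. The fall of CCR7 was kept over all barcodes with at least 300 UMIs, of which those under 500 UMIs all came from WT replicate 2. The shares of the 3 classes kept their direction where the class formed. An exception is cytotrophoblast-like cells without integration, which at 0.289% of WT replicate 2 have no readable direction. Among the other clusterings a column-like class formed only at resolution 1.0 and without doublet removal, so its lower share was not tested in the rest. A cluster with TUBB2A, KRT14 and NPPB among its top genes was counted as cytotrophoblast-like under 2 other cell filters. It had 3 column markers raised with up to 50% mitochondrial UMIs, and 1 with at least 500 genes and under 10% mitochondrial UMIs. With up to 50% mitochondrial UMIs, both knockout libraries no longer lay outside both WT libraries for cytotrophoblast-like cells. The same held for mitotic cells with at least 500 genes and under 10% mitochondrial UMIs. Their shares were then 7.02% and 6.13% in WT and 6.95% and 12.8% in the knockout. These shares include a cluster led by HELLPAR, L3MBTL1 and KCNQ1OT1 rather than by mitotic genes. It had 5 mitotic and 8 cytotrophoblast markers raised. The rise of the syncytiotrophoblast-like share was 5.90 to 12.8 percentage points with 1 library left out, the lowest without knockout replicate 2. At resolution 1.0 it was 5.45 percentage points, from a mean of 2.76% in WT to 8.21% in the knockout. Size factors in place of TMM and no doublet removal left the numbers of changed genes within 1.5 times the reported ones, with 206 and 204 of the 206 genes over all cells shared. Of 131 comparisons with an alternative, 77 gave a number of genes or lists within 1.5 times the reported one, a share difference of the same sign or the same call of CCR7. Beyond that, 33 gave more genes or lists, 19 fewer and 2 the other sign. DESeq2 called 1489, 1235, 258 and 126 genes, which included the 206, 250 and 62 reported ones and 64 of the 68 column-like ones, and edgeR without a filter on low counts 1961, 1876, 713 and 394. Leaving out 1 library, with the lone one assumed to vary like the other genotype, gave 437 to 1039, 312 to 1042, 229 to 386 and 103 to 280 genes, the lowest without knockout replicate 2 except in syncytiotrophoblast-like cells, where it was without WT replicate 2. The cause of these higher numbers was not tested. With at least 500 genes and under 10% mitochondrial UMIs, 88, 92 and 360 genes changed, and no column-like class formed. Thinned cells gave 60, 88, 27 and 1 genes, from fewer cells, UMIs and genes tested by construction, and 55 of the 60 were among those reported. Resolution 1.0 gave 105 in column-like cells. Without integration 116 changed in syncytiotrophoblast-like cells, WT replicate 2 had 7 cytotrophoblast-like cells and was left out there, and no column-like class formed.

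Lists past the threshold numbered 7, 6, 3 and 10. With an estimated correlation camera called 0, 0, 0 and 0, with 1, 1, 0 and 0 at unadjusted p under 0.05, and fry called 0 in each after adjustment. Leaving out 1 library gave 1 to 10, 4 to 8, 1 to 4 and 5 to 14 lists. It was 1 without WT replicate 1 and 2 without knockout replicate 2 over all cells, 1 without WT replicate 2 or knockout replicate 2 in syncytiotrophoblast-like cells, and 5 without knockout replicate 2 in column-like cells. The number of genes whose effect differed between classes was 424 in all and 129 to 553 with 1 library left out, the lowest without knockout replicate 2. The part between column-like and cytotrophoblast-like cells, 14, was 27 to 109 with 1 library left out and 138 without a filter on low counts. The difference in cycling share, 2.71 percentage points, ranged from −1.68 to 7.11 with 1 library left out and turned to −0.795 without WT replicate 1 and −1.68 without knockout replicate 2, so it has no settled sign. The causes were not tested.

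The labels do not say that a replicate number marks a shared experiment, and there are 2 pairs. With the replicate number as a block 5211, 5272, 2685 and 834 genes and 11, 6, 2 and 10 lists passed, and the deviations of same-numbered libraries correlated across genes at 0.599, 0.589, 0.403 and 0.399, where genes are not independent replicates.

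A limit of 50% mitochondrial UMIs, lists on thinned cells and leaving out genes of chromosomes 10, 11 and 20 were chosen after seeing the data. The first gave 182 genes and 8 lists in syncytiotrophoblast-like cells and formed no column-like class, the second 1 list in syncytiotrophoblast-like and 3 in column-like cells, and the last 35 genes in column-like cells, where 2, 9 and 2 of the 68 lie on those chromosomes and the cause of the other losses was not tested. Simulated 2-fold changes were recovered in 3.16% to 7.37% of genes at these library sizes, and by the interaction fit in 40.8%. With a simulated effect shared by replicates of one number the fit without a block recovered 0% to 2.11%, and that with the replicate number as a block 26.8% to 29.9%. The simulations did not vary depth.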

Other observations

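Both tests of chromosome 20 were chosen after its lower expression was seen.

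P4HTM, a prolyl hydroxylase gene, had 329 and 572 UMIs in WT and none in either knockout library. The imprinted genes PHLDA2 and CDKN1C rose in column-like cells, where ZFAT and MEST rose too, and these genes lie on chromosomes 11, 8 and 7.

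Expression was lower along the whole of chromosome 20 in the knockout, and a candidate explanation is that the lines carry different numbers of copies of it. A few strongly changed genes are argued against, since 82.3% of its 378 genes lay below the median of all genes in cytotrophoblast-like cells (bootstrap 95% interval 78.3% to 86%). A difference in copies stays open, with class medians from −0.570 to −0.506, the one nearest 0 in cytotrophoblast-like cells, since such a difference goes with the genotype here. In single pairs of libraries of this class, the median of chromosome 20 ran from −0.478 to −0.305 for knockout over WT. It was 0.05 between the WT libraries and 0.13 between the knockout libraries. On the same measure chromosome 19 differed by 0.265 between the knockout libraries, while chromosome 10 was at 0.0744 to 0.163 for knockout over WT. Shifts as small as that of chromosome 10 thus also arose between libraries of 1 genotype, on other chromosomes. Windows with shifts of either sign also lay on chromosomes 5, 10, 11 and 18, for example −0.97 at the end of chromosome 5 and 0.98 on chromosome 11. As a hypothesis, WT and knockout lines may differ in copy number independently of CCR7, and since no DNA was measured and 1 line stands for each genotype, the direction of gain or loss cannot be read from these counts.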
